A study of Mus musculus with 12 samples.

How the data were processed

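RNA was measured on 12 arrays from cultures of mouse megakaryocytes, the bone marrow cells that release platelets. Per the labels' protocols, hematopoietic stem cells of male C57BL/6 bone marrow were grown for 3 days in thrombopoietin at 100 ng per ml, kept overnight in medium with 10% charcoal-stripped serum, and purified as day 4 cells on an albumin gradient with steps of 0, 1.5 and 3%. Each culture was then divided between 100 nM dexamethasone, a synthetic glucocorticoid, and its vehicle for 6 h. There were 6 cultures, so 6 arrays per treatment, numbered 1 to 6 in both groups. These are the labels' replicate numbers; replicates 1 to 6 are the cultures that the labels number 1, 4, 5, 6, 7 and 8, and culture 1 to 6 in this text means the replicate number. Per the labels' protocols, whole-transcript cDNA was made from 50 ng of RNA and tagged with biotin, so the arrays have 1 colour.

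The values used were the authors' deposited log2 values for 72688 probe sets on each of the 12 arrays. The background correction, normalization, summarization and array annotation are not given in the sources used here. The log2 scale was read from the values, which run from 2.07 to 19.93 with no centring of genes. How values above 16 arose was not tested, so a fold here is a fold on the deposited scale. The array medians were 5.60, 5.67, 5.67, 5.61, 5.58 and 5.67 for vehicle cultures 1 to 6, and 5.62, 5.60, 5.60, 5.57, 5.61 and 5.66 for dexamethasone cultures 1 to 6. The number of arrays limits the precision, and signal over background differed between genes. The median of the negative control probe sets lay between 6.15 and 6.39 on the 12 arrays. Their 95th percentile lay between 9.98 and 10.39, and 11.9 to 14.1% of named probe sets lay above it.

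The design written before the data were examined asked for quantile normalization if medians or quartiles differed between arrays, and it set no tolerance. Medians lay within 0.10 of each other, lower quartiles within 0.14 and upper quartiles within 0.16. Before any test this was read as a table already normalized, and the values were used as deposited. A literal reading of that rule would have made quantile normalization the main setting. It is reported as an alternative, and the balance of higher and lower genes differs under it.

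Of the 72688 probe sets, 65956 were transcript clusters, 5222 negative controls, 1324 positive controls, 163 spike-in controls and 23 background controls. A table of the array's annotation gave 1 gene symbol to 30604 probe sets and several to 2146, and 33206 clusters had none there. Gene numbers of 22818 named probe sets matched the RefSeq table of assembly GRCm38.p6, which updated 827 symbols. No gene was named from a probe set with several symbols, which leaves Gp1ba among others without a value. Each gene was represented by its probe set with the highest mean over all 12 arrays, a rule blind to treatment. A gene entered the test if it lay above the 25th percentile of its array on at least 6 of the 12 arrays, which kept 24265 of 30142 genes.

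The fit was limma 3.58.1 in R 4.3.3, lmFit and eBayes without trend or robust options, with culture as a block, two-sided, and p adjusted by Benjamini-Hochberg over all genes tested. A gene was called past the threshold at an adjusted p under 0.05. All adjusted p-values in the text come from limma. The block follows from the treatment protocol, which states that cultures were divided, with numbers shared by both groups. As a check of the pairing, deviations from the group means were correlated over genes between arrays of the same number. These correlations ran from 0.049 to 0.247 with a mean of 0.157, against a mean of -0.032 for arrays of different numbers. They were over 0.1 in 4 of the 6 pairs, and 2 of the 6 cultures matched their own number best. The replicates are separate cultures, and whether each came from separate mice is not given in the sources used here.

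Gene lists were fixed before the data were examined. There were 24 lists with 624 distinct genes, of which 552 matched a named probe set. For each list the text gives the members past the threshold over all genes tested, and the members past it when adjusted over the list alone. Lists were also tested with camera at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry, each adjusted over the 24 lists. Camera compares a list with the other genes. For the alternative with culture as a random effect, a form of camera was run on the genes' t values in place of the expression values. Fry asks whether the members move on balance in 1 direction and makes no comparison with other genes. In its mixed form it asks whether members change in either direction.

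Genes to be named were chosen by rule. They are the 10 largest rises and the 10 largest falls among genes past the threshold that moved the same way in all 6 pairs. Any member of the glucocorticoid receptor target list could be named, and of each other list up to 4 members with the largest change among those past the threshold, or up to 2 with the highest mean where none passed. Nr3c1, Nr3c2, Itga2b, Pf4 and Gp1ba were fixed by name. The rule for the largest rises skipped 3 predicted genes without a name. Genes named outside the rule are marked as such.

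The fit was tested on simulated data for this comparison, with 200 of 24265 genes changed in each of 20 runs and genes drawn independently. It recovered 97.9% of changes of 1 on the log2 scale and 79.9% of changes of 0.5, and 4.85% of its calls were false. Smaller changes were not simulated, whereas the genes called in the data had a median absolute change of 0.30. The recovery of such changes is therefore not known. Alternatives tried were a fit with no block, no filter or a filter at the 50th percentile, quantile normalization, centring on array medians, a floor at the 25th percentile, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust, culture as a random effect, array weights, stricter thresholds, and leaving out each culture. Added after seeing the data were a filter at the negative control median, leaving out cultures 2 and 3 together, and a fit of all probe sets including unnamed and control ones. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.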

Results

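Dexamethasone and vehicle were compared on 12 arrays, 6 per treatment, from 6 megakaryocyte cultures that were each divided between the treatments for 6 h. The series asks how glucocorticoids regulate the megakaryocyte transcriptome. Of 30142 named genes, 24265 were tested, and each array gave 1 log2 value per gene. Arrays of the same treatment correlated with r between 0.990 and 0.994 over all probe sets, and the median SD of a gene was 0.125 in vehicle and 0.107 in dexamethasone.

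After 6 h of dexamethasone, 15 of 26 tested glucocorticoid receptor targets had risen, 1 had fallen and 10 did not pass the threshold. Among them Map3k6, which rose, and several that did not pass lay below the negative control median on all arrays. Of 28 inflammatory cytokines and chemokines 7 had fallen, none had risen and 21 did not pass. The median level of these 28 was 6.35, near the negative control median. Rasd1, a small G protein named for its induction by dexamethasone, rose most among named genes, from 6.34 ± 0.24 to 11.81 ± 0.51 (log2, SD, n = 6), a 44.1-fold change from a vehicle level at the negative control median, below which 1 of 6 vehicle arrays lay. Cxcl3, a neutrophil-attracting chemokine, fell most, from 10.36 ± 0.21 to 8.07 ± 0.21, a 4.88-fold change. The platelet chemokine Pf4, at 18.94 ± 0.03 and 18.95 ± 0.04, differed by 0.01 with an adjusted p of 0.921. Pf4 lay near the top of the scale, where the array maxima were 19.82 to 19.93. Whether a change could show there was not tested. The integrin Itga2b was 15.37 ± 0.05 and 15.51 ± 0.07, a difference of 0.14 with an adjusted p of 0.083.

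In all, 2900 genes passed the threshold, 11.95% of those tested, with 1794 higher and 1106 lower in dexamethasone. Most of these changes were small: the median absolute change was 0.30 on the log2 scale, and 103 genes were at least 2-fold higher and 9 at least 2-fold lower. Of all tested genes, 19.5% moved the same way in all 6 pairs, against 3.125% by chance. Of the 2900 genes 2730 did, a share that follows in part from their selection by a paired test. The balance of directions depended on the scaling. Higher genes made up 61.9% of calls as deposited, 44.9% after quantile normalization and 70.3% after centring on array medians. Some settings gave more calls: 3155 after quantile normalization, 3159 with culture as a random effect and 3231 with trend and robust. Stricter filters gave 3351 of 16442 genes above the 50th percentile and 3427 of 13050 above the negative control median. Leaving out culture 3 gave 1878 genes, 1164 higher and 714 lower, leaving out culture 4 gave 1178 higher, leaving out culture 6 gave 712 lower, leaving out cultures 2 and 3 together gave 1269 (731 and 538), and fitting unnamed and control probe sets as well gave 1482 (956 and 526).

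**Figure D1:**
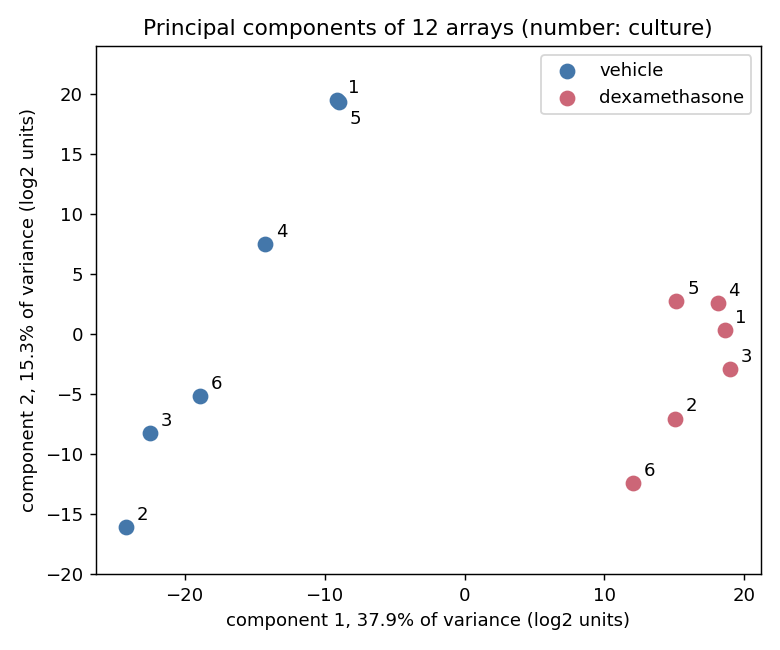
Each point is an array, placed by the first and second principal components of 24265 genes (log2 units) and numbered by culture. The first component, 37.9% of the variance, separates the treatments, with vehicle between -24.2 and -8.96 and dexamethasone between 12.0 and 19.0.

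After Rasd1, the largest rises were those of Tmem273 (4.03 on the log2 scale, SE 0.07), the lipoprotein receptor gene Lrp8 (3.39, SE 0.09), Bnip3, a mitochondrial regulator of mitophagy (3.38, SE 0.08), and Pfkfb3, an enzyme that drives glycolysis (3.35, SE 0.07). They were followed by the growth factor Bmp2 (3.03, SE 0.13), the mitotic inhibitor kinase Wee1 (2.87, SE 0.13), the Golgi mannosidase Man2a1 (2.85, SE 0.07), Mettl7a1 (2.75, SE 0.05) and Tsc22d3 (2.48, SE 0.06). Adjusted p was at most 2.62e-06 for these 10 genes, which the naming rule took from genes that moved the same way in 6 of 6 cultures. After Cxcl3, the largest falls were those of Pxdc1 (-1.37, SE 0.08), the translational repressor Nanos1 (-1.30, SE 0.08), the G protein signalling regulator Rgs16 (-1.22, SE 0.12) and Tubb1, the beta tubulin of the platelet microtubule coil (-1.14, SE 0.06). Next came interleukin 1 alpha, Il1a (-1.13, SE 0.05), granzyme B, Gzmb (-1.11, SE 0.05), the interferon-induced Ifit1 (-1.06, SE 0.09), the growth factor receptor Kdr (-1.01, SE 0.06) and the actin-severing Scin (-0.96, SE 0.06). Adjusted p was at most 0.000329 for these falls, which the same rule took from genes lower in 6 of 6 cultures.

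**Figure D2:**
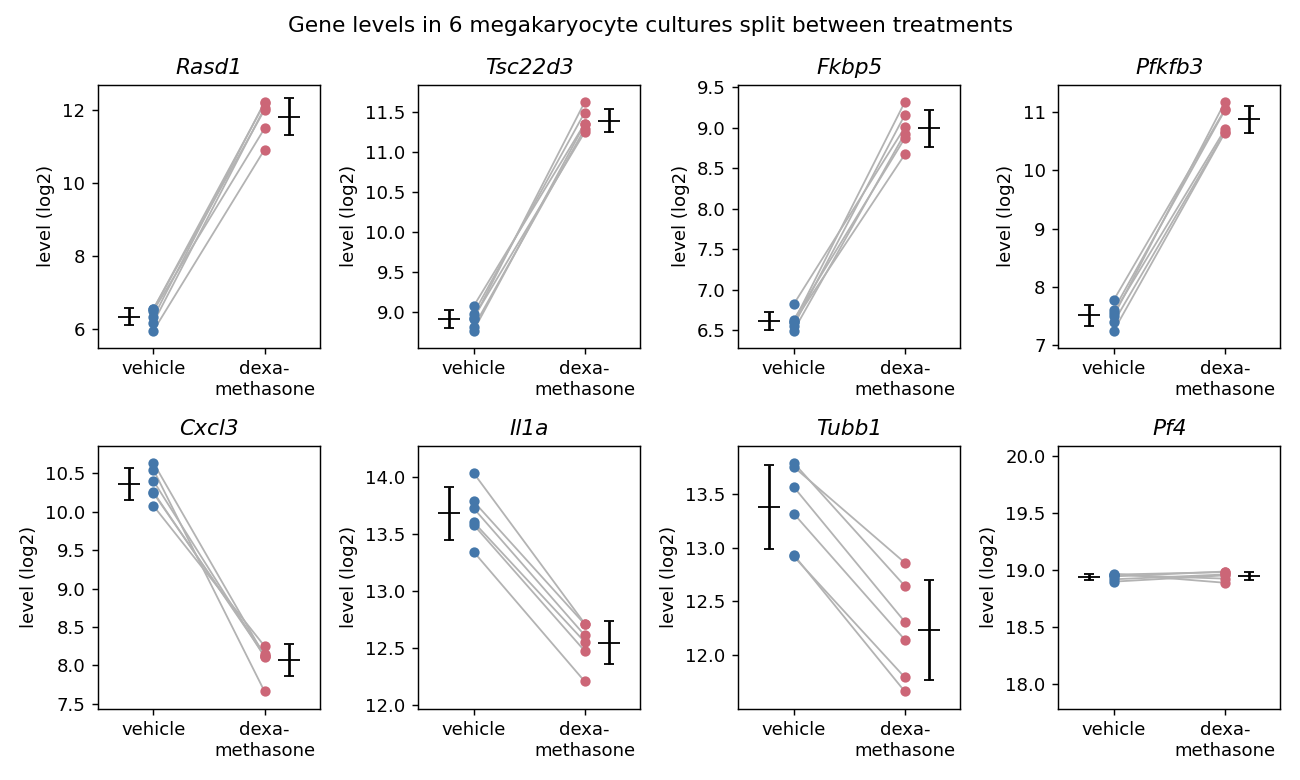
Levels (log2) of 8 genes in vehicle and dexamethasone arrays, with grey lines joining the arrays of a culture and black marks giving the mean and SD of 6 arrays. Every culture rose for Rasd1, Tsc22d3, Fkbp5 and Pfkfb3 and fell for Cxcl3, Il1a and Tubb1, while Pf4 stayed between 18.9 and 19.0. Axis ranges differ between genes.

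Among the 24 lists, the glucocorticoid receptor targets had the largest median change. Of 26 tested, 15 rose, 1 fell and 10 did not pass, and 16 rose and 2 fell when adjusted over the list alone. Tsc22d3, which encodes the anti-inflammatory protein GILZ, rose 5.57-fold, and Fkbp5, a co-chaperone that dampens the receptor, rose 5.19-fold. The phosphatase Dusp1 rose 4.45-fold, the transcription factors Zbtb16 and Klf9 rose 4.40-fold and 3.92-fold, and the growth inhibitor Ddit4 rose 3.55-fold. The metallothioneins Mt2 and Mt1 rose 4.27-fold and 2.70-fold from already high levels of 15.20 ± 0.16 and 14.56 ± 0.16. Per1 rose 2.36-fold and Tgm2 1.56-fold. Sesn1 fell 1.48-fold. Sgk1, a target in many tissues, was 5.78 ± 0.09 and 5.76 ± 0.04 (adjusted p = 0.875) and lay below the negative control median on all arrays. So did Angptl4, Cd163, Errfi1, Fam107a, Il1r2 and Mertk, which did not pass, and Map3k6, which counts among the rises. Lcn2, also among the rises, lay below it on 6 of 6 vehicle and 5 of 6 dexamethasone arrays. Its call was lost under 8 of 18 other settings. The list's median change was 0.37, and camera gave an adjusted p of 1.56e-10, with adjusted p = 0.133 with an estimated correlation. Fry gave an adjusted p of 4.28e-05 for a rise on balance.

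Of 28 inflammatory cytokines and chemokines tested, 7 fell, none rose and 21 did not pass, and 9 fell when adjusted over the list alone. The median level of the 28 was 6.35, within the 6.15 to 6.39 of the negative control medians. A fall of the dimmer members may therefore not have shown. Besides Cxcl3 and Il1a, the interleukin 12 subunit Il12a fell by 0.77 (SE 0.05) and the monocyte chemokine Ccl2 fell by 0.70 (SE 0.07), each in 6 of 6 cultures. Camera gave an adjusted p of 6.23e-05, with adjusted p = 0.088 with an estimated correlation. Interferon-stimulated genes also fell, 7 of 26 with none higher and 19 not past the threshold, and 7 when adjusted over the list alone. Ifit2 fell by 0.79, Gbp2 by 0.45 and Ifit3 by 0.43, each in 6 of 6 cultures. The adjusted p was 0.014 by camera and 0.153 with an estimated correlation. Fry gave adjusted p of 4.51e-05 for the cytokines and 0.00073 for the interferon-stimulated genes, both for a fall on balance.

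Among NF-kappaB feedback and signalling genes, 2 of 21 rose and 3 fell, and 2 rose and 5 fell when adjusted over the list alone. The other 16 did not pass. Tnfaip3 and Nfkbia, which restrain the pathway, rose 1.65-fold and 1.34-fold, and Tnip3 fell 1.61-fold. Camera gave an adjusted p of 0.271, and fry 0.035 for a fall on balance.

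The receptor for dexamethasone, Nr3c1, was 9.04 ± 0.07 in vehicle and 8.87 ± 0.06 in dexamethasone, a difference of -0.17 with an adjusted p of 0.053, lower in 6 of 6 cultures. It passed the threshold under 7 of 19 other settings, among them quantile normalization with an adjusted p of 0.0209, over a range from 0.014 to 0.199. The mineralocorticoid receptor Nr3c2 lay below the negative control median on all arrays in both groups. In the list of receptor, chaperone and steroid enzyme genes, 7 of 19 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone. The falls included the coactivator Ncoa3 (-0.38), the Hsp90 co-chaperone Stip1 (-0.30) and the heat shock protein Hspa4 (-0.28), and the rise was that of Fkbp5. The list's adjusted p was 0.0048 by camera for a fall, and adjusted p = 0.515 with an estimated correlation, and fry gave 0.0306 for a fall on balance. With culture as a random effect, where a form of camera was run on the genes' t values, the list's adjusted p was 0.191. Among 20 other settings, this one included, it ranged from 0.00041 to 0.191.

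**Figure D3:**
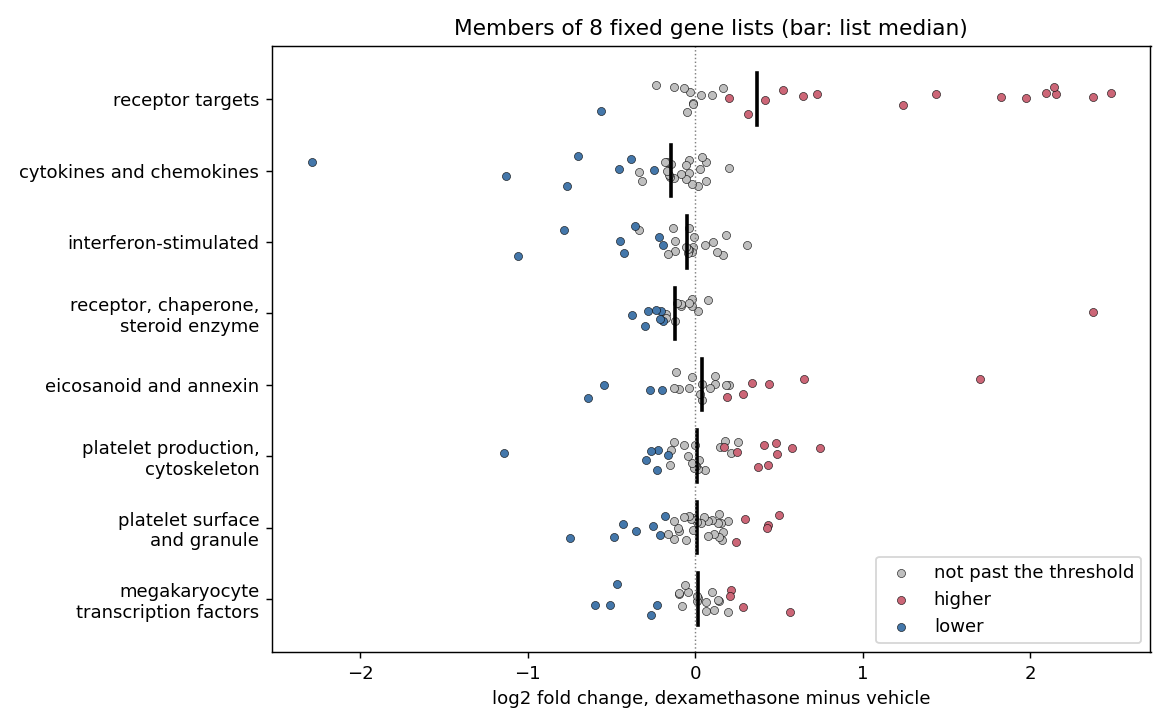
Each point is a tested member of 1 of 8 gene lists, at its log2 fold change of dexamethasone minus vehicle, coloured by whether it passed the adjusted p threshold of 0.05, with a bar at the list median. The medians are 0.37 for receptor targets and -0.15 for cytokines and chemokines, and those of the 3 platelet and megakaryocyte lists lie between 0.008 and 0.014. Vertical scatter within a list is arbitrary.

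Genes that define megakaryocytes went both ways. Of 37 platelet surface and granule genes, 5 rose and 7 fell, and 11 rose and 10 fell when adjusted over the list alone. The coagulation factor F13a1 rose by 0.50 (SE 0.05) and the von Willebrand receptor subunit Gp9 by 0.44 (SE 0.06), whereas the vascular growth factor Angpt1 fell by 0.75 (SE 0.06) and the ADP receptor P2ry1 fell by 0.48 (SE 0.06). The median change was 0.008, the mean was -0.001 and camera's direction was up with an adjusted p of 0.791. Of 24 megakaryocyte transcription factors, 4 rose and 5 fell, and 6 rose and 5 fell when adjusted over the list alone. Mef2c fell by 0.60, Srf by 0.51 and Ets1 by 0.47, while Egr1 rose by 0.56. The median was 0.014, the mean -0.014 and camera's direction down, with an adjusted p of 0.960.

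Genes of platelet production and the cytoskeleton split, with 9 of 32 higher and 6 lower, and 12 higher and 8 lower when adjusted over the list alone. Tubb1 fell from 13.38 ± 0.39 to 12.24 ± 0.47, in 6 of 6 cultures. The myosin light chain kinase Mylk rose by 0.74 (SE 0.06), the membrane skeleton protein Sptb by 0.58 (SE 0.06) and the actin regulator Was by 0.49 (SE 0.06). Camera gave an adjusted p of 0.271.

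Among eicosanoid and annexin genes, 6 of 23 rose and 4 fell, and 7 rose and 4 fell when adjusted over the list alone. Ltc4s, which makes leukotriene C4, rose 3.25-fold from a vehicle level of 6.25 ± 0.17, with 2 of 6 vehicle arrays below the negative control median. Alox5ap, the 5-lipoxygenase activating protein, rose 1.57-fold. The phospholipase Pla2g4a, which releases arachidonic acid, fell 1.56-fold, and the prostaglandin D synthase Hpgds fell 1.46-fold. Camera gave an adjusted p of 0.271 and fry an adjusted p of 0.018 for a rise on balance. Among chemokine, cytokine and growth factor receptors, 10 of 31 rose and 5 fell, and 12 rose and 6 fell when adjusted over the list alone, with an adjusted p of 0.186 by camera. The interleukin 10 receptor chain Il10ra rose by 0.78 and the chemokine receptor Cxcr4 fell by 0.52. Ccr4 rose by 1.11 but lay below the negative control median on all arrays, and with a floor at the 25th percentile its change was 0.52.

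Clock genes went both ways, with 4 of 19 higher and 5 lower, and 5 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.756). Besides the rise of Per1, Cry2 rose by 0.46, while Nr1d1 and Bhlhe41 fell by 0.84 and 0.48. Of 24 MAP kinase phosphatase and immediate early genes, 4 rose and 5 fell, and 7 rose and 5 fell when adjusted over the list alone. Besides Dusp1, Dusp10 rose by 0.52, and Dusp4 fell by 0.62. The list's median was -0.013, its mean 0.078 and camera's direction up, with an adjusted p of 0.960.

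Of 26 genes of glucose, amino acid and lipid metabolism, 6 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. Pfkfb3 rose 10.2-fold and its relative Pfkfb4 rose 1.48-fold, the lipid regulator Pparg rose 1.39-fold, and hexokinase 2, Hk2, fell 1.43-fold, with 1 of 6 dexamethasone arrays below the negative control median. Camera gave an adjusted p of 0.186, and fry an adjusted p of 0.0049 for a rise on balance. Of 22 unfolded protein and amino acid stress genes, 4 rose and 7 fell, and 4 rose and 8 fell when adjusted over the list alone. The chaperone Hspa5 fell by 0.35, the disulfide isomerase Pdia6 by 0.44 and the asparagine synthetase Asns by 0.49, while Ppp1r15a rose by 0.74. Camera gave an adjusted p of 0.072 for a fall, 0.00999 after quantile normalization and a range from 0.00999 to 0.132 over 20 other settings, and adjusted p = 0.641 with an estimated correlation. Fry gave an adjusted p of 0.0329 for a fall on balance. Of 18 cholesterol synthesis genes, 1 rose and 2 fell, the same numbers when adjusted over the list alone. Their median was 0.037, their mean -0.005 and camera's direction up, with an adjusted p of 0.960.

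Cell cycle and mitosis genes showed 4 of 35 higher and 6 lower, and 6 higher and 7 lower when adjusted over the list alone (camera adjusted p = 0.778). The replication helicase Mcm6 fell by 0.48 and cyclin D2, Ccnd2, by 0.46, and E2f8 rose by 0.35. Of 25 Bcl2 family, caspase and other apoptosis regulators, 7 rose and 3 fell, and 8 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.186). The survival factor Bcl2l1 rose by 0.35 and the pro-apoptotic Pmaip1 rose by 0.52, while the inhibitor of apoptosis Birc2 fell by 0.86 (SE 0.05).

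Markers of other cells that the cultures could hold were mostly dim. Of 18 neutrophil genes, 2 rose and 4 fell, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.186). S100a9 was 12.54 ± 1.01 in vehicle and 11.77 ± 1.49 in dexamethasone, and S100a8 was 12.36 ± 1.19 and 11.85 ± 1.56. Their level differed far more between cultures than between treatments, and it was lowest in culture 2. The falls, 0.77 and 0.51 below vehicle in log2 terms, had adjusted p of 0.029 and 0.047 and were seen in 6 of 6 cultures. Culture 2 had the largest, -1.86 for S100a9 and -1.33 for S100a8, against -0.98 to -0.27 and -0.63 to -0.18 in the other cultures. Without cultures 2 and 3 the changes were -0.52 and -0.32. Both calls ended with culture as a random effect (adjusted p of 0.376 and 0.601) and without the block (0.488 and 0.689). Leaving out culture 1, 3 or 4 ended both calls while the changes stayed near those of all cultures (-0.73, -0.79 and -0.83 for S100a9, -0.49, -0.52 and -0.57 for S100a8), with adjusted p of 0.0745, 0.0655 and 0.0531 for S100a9 and 0.103, 0.0997 and 0.0677 for S100a8, and leaving out culture 5 or 6 ended that of S100a8 at 0.0615 and 0.0579 with changes of -0.57 and -0.58.

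Of 10 erythroid genes, 1 rose and 1 fell, also when adjusted over the list alone; the fall was that of the transferrin receptor Tfrc (-0.65, SE 0.06), and camera gave an adjusted p of 0.735. Of 22 monocyte and macrophage genes, 1 fell, also when adjusted over the list alone, the chemokine receptor Ccr2, which fell by 0.42 to a level below the negative control median on all 6 dexamethasone arrays (camera adjusted p = 0.271). Of 13 mast cell, basophil and eosinophil genes, 2 rose and 1 fell, and 3 rose and 1 fell when adjusted over the list alone, with the mast cell protease Cpa3 higher by 0.64 (camera adjusted p = 0.324, fry 0.0425 for a rise on balance). Of 18 lymphocyte genes, 1 rose and 1 fell, also when adjusted over the list alone, the fall being that of Gzmb from 13.91 ± 0.33 (camera adjusted p = 0.186, fry 0.0467 for a fall on balance). Of 18 stem and progenitor genes, 3 rose and 5 fell, and 3 rose and 6 fell when adjusted over the list alone, among them Mllt3, which fell by 0.40 (camera adjusted p = 0.165). Fry gave that list an adjusted p of 0.00861 for a fall on balance. Of 18 stromal and endothelial genes, Kdr alone fell, also when adjusted over the list alone (camera adjusted p = 0.22, fry 0.00743 for a fall on balance). The median levels of the mast cell, lymphocyte and stromal lists were 5.89, 5.37 and 5.29, below the negative control median. Their fry values thus rest largely on dim genes, without a comparison with other genes. For the lists without a fry value here, its adjusted p for a move on balance was at least 0.0614.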

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

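The tests of the Tubb1 fall against the share of megakaryocytes and against other beta tubulins were chosen only after the values they use were seen; the other tests in this part were chosen before. Levels and differences here are on the log2 scale. Among 114 named genes, 14 of 228 groups of 6 arrays and 4 of 114 sets of 6 pair differences held a value far from the others, and so did 1 of 22 sets of array measures. Chance alone marks about 1 in 20 groups.

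In vehicle arrays, values far above the others were those of Aqp1 in culture 2 (6.36, others 6.04 to 6.16), Bcl2l1 in culture 1 (10.13, others 9.93 to 10.00), Dusp10 in culture 3 (8.57, others 7.91 to 8.12) and Tgm2 in culture 1 (6.88, others 6.29 to 6.50). Sesn1 in culture 2 was far below (11.55, others 11.78 to 11.88). In dexamethasone arrays, values far below the others were those of Cxcl3 in culture 1 (7.66, others 8.11 to 8.25), Stard4 in culture 1 (12.27, others 12.33 to 12.37), Gzmb in culture 2 (12.25, others 12.78 to 13.01) and Tmem273 in culture 2 (10.55, others 10.96 to 11.10). The same held for Hspa4 in culture 3 (13.69, others 13.76 to 13.80), E2f8 in culture 6 (11.01, others 11.30 to 11.48) and Stip1 in culture 6 (11.53, others 11.89 to 12.06). Mertk in culture 1 (5.13, others 4.89 to 4.97) and Pdia6 in culture 5 (11.43, others 11.23 to 11.29) were far above.

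Among differences of dexamethasone minus vehicle within a culture, those far from the others were Dusp4 in culture 4 (-0.0885, others -0.81 to -0.63), Hspa5 in culture 2 (-0.16, others -0.43 to -0.33), Il1a in culture 4 (-1.32, others -1.13 to -1.05) and Tnfaip3 in culture 6 (0.38, others 0.70 to 0.87). The lower quartile of the dexamethasone array of culture 6 was 4.87, with the others between 4.79 and 4.81.

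Probe sets outside the comparison also carried a signal. Of 1816 clusters with several gene symbols, 86 passed the threshold, 53 higher and 33 lower, and of 22902 clusters without a symbol, 750 passed, 561 higher and 189 lower. Among 4300 negative controls fitted with them, 68 (1.58%) passed, with changes from -2.21 to 1.62. Of 1279 positive controls 87 (6.80%) passed and of 94 spike-in controls 1, against 6.06% of clusters with 1 symbol in the same fit.

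The split of the arrays into treatments gave 2900 genes past the threshold with the block. Of the 32 splits that part every pair, 1 gave as many, the real one, and the highest of the others gave 0. Those others leave the treatment difference in their residual spread, which lowers their counts. They therefore do not show how many genes chance alone would give. Without the block the real split gave 2452 genes. Among 100 splits, drawn from the 462 possible, 1 gave as many, and the highest of the others gave 2. These splits ignore the pairing and carry the treatment difference in the same way, so they add no measure of chance.

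The fall of Tubb1 (-1.14, lower in 6 of 6 cultures) is a pattern to follow up, since it is the beta tubulin of platelets. A lower share of megakaryocytes on the dexamethasone arrays would lower the platelet surface and granule genes as well. The 37 tested had a median change of 0.00825, quartiles of -0.12 and 0.14, and a lowest change of -0.75. That median is the change of Pf4, which lay near the top of the scale. The values were seen before the test was chosen. They argue only against a loss of megakaryocytes that lowers these genes as far as Tubb1. Hybridization shared with other beta tubulins is argued against by the 9 other named Tubb genes, with a median of 0.0285 and a lowest change of -0.29. A scaling difference of bright probe sets is argued against by 463 genes within 0.5 of the vehicle level of Tubb1, with a median of 0.0259 and a lowest change of -1.13. A fault of the single named probe set of Tubb1 stays open, and a regulated fall of its transcript may be a candidate explanation only as a hypothesis.

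The falls of S100a9 and S100a8 had a mean of -0.64, on levels that were lowest in culture 2 in both groups. Culture 2 also had the largest falls, -1.86 and -1.33, and so weighs on that mean. Fewer neutrophil-lineage cells on the dexamethasone arrays could account for the falls, and would lower the other abundant neutrophil genes alike. Of the 16 other neutrophil genes tested, 0 lay above a level of 8, where 5 were needed for the test, so the test decides nothing. Their median change was -0.07, and they went both ways, with Camp at -0.49 and Mmp8 at 0.47, on vehicle levels of 7.51 and 6.21. Fewer such cells and a fall within them cannot be told apart here, because no other neutrophil gene was bright enough. Which cells of the cultures held the S100a9 and S100a8 transcripts was not measured, so the falls cannot be assigned to a cell type.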

How the results depend on the processing

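The filter at the negative control median, leaving out cultures 2 and 3 together, and the fit with unnamed and control probe sets were chosen after seeing the data. Of 114 named genes, 100 passed the threshold, and 83 of them passed under each of the 17 to 19 refits that tested them, leaving aside the fit with unnamed and control probe sets and the stricter thresholds, while 17 were lost under at least 1, 4 (Nr3c1 under 7, Itga2b and Rgs2 under 3, Txnip under 1) passed only under another setting and 0 changed sign. Leaving out each culture gave from 1878 (without culture 3) to 2331 genes, 1164 to 1520 higher and 712 to 853 lower. Without culture 3 there were 714 lower, and without culture 4 there were 1178 higher. Each of these fits has fewer arrays.

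Quantile normalization raised the number of lower genes to 1738, and the cause was not tested. Centring on medians reduced it to 726. Centring shifts the change of every gene by the same amount. With it, the median change of all tested genes went from -0.0126 to 0.0080. An adjusted p under 0.01 left 1310 genes (862 higher, 448 lower), and a 1.5-fold bound left 395 (322 and 73), by construction; 15 and 50 of the 100 named calls missed these bounds. Without cultures 2 and 3 there were 1269 (731 and 538), with fewer arrays, and all 17 of the calls counted as lost above ended there, those of Dusp4, E2f8, Ifit3 and Nfkbia in no other of these refits, at changes of -0.60, 0.27, -0.32 and 0.37. Fitting unnamed and control probe sets as well left 1482 (956 and 526), with more tests and prior degrees of freedom of 2.36 in place of 3.74; 11 named calls were lost, 10 of them among the 17, and that of Stip1 with an adjusted p of 0.054. Without the block for pairing the count was 2452, and no list call changed. There 8 named calls were lost, those of Camp, Ccnb2, Ebp, Kit, Lcn2, Mcpt8, S100a9 and S100a8, with adjusted p from 0.0598 to 0.689. Culture as a random effect ended the calls of Ccnb2, Kit, Lcn2, Mcpt8, S100a9 and S100a8, with adjusted p from 0.0504 to 0.601.

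Of the 4 lists past the threshold by camera, 0 passed with an estimated correlation: adjusted p was 0.133 for receptor targets, 0.0878 for cytokines, 0.515 for chaperones and 0.153 for interferon-stimulated genes. The unfolded protein list passed under 8 of 20 other camera settings, the stem and progenitor list under 2 and the metabolism list under 1, with lowest adjusted p of 0.00999, 0.0353 and 0.00577. By fry, which makes no comparison with other genes, 12 passed. The chaperone list had 0.191 with culture as a random effect, where a form of camera was run on the genes' t values. Whether the random effect or the change of list test caused this was not tested. The interferon list's 0.014 misses a bound of 0.01. Leaving out each culture gave 2.19e-11 to 4.27e-09 for receptor targets, 3.05e-06 to 0.000348 for cytokines, 0.00324 to 0.0154 for chaperones and 0.00359 to 0.0337 for interferon-stimulated genes. Signal over background limits dim genes: 243 calls lay below the negative control median on all 12 arrays.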

Other observations

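The sets of genes in this part were formed after large changes in their members had been seen, while the tests on the members not yet seen were chosen before those values were. The genes named here were chosen after their values were seen. Genes of purine transport and salvage stood among the rises, with Slc43a3 higher by 2.33 on the log2 scale, Gda by 2.18, Slc28a2 by 1.97 (from 6.27, with 3 of 6 vehicle arrays below the negative control median), Ahcy by 1.96 and Nt5e, which makes adenosine, by 1.90. Of the 8 such genes seen first 2 fell, the receptors P2ry1 by 0.48 and P2ry12 by 0.43. Gclc, the limiting enzyme of glutathione synthesis, was higher by 2.12, and the glutathione genes Gsr and Mgst3 by 1.20 and 0.93. Granzyme C, Gzmc, fell by 0.76 beside granzyme B.

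A hypothesis was that purine transport, salvage and receptor genes rise together. Of 24 members not yet seen, 6 rose, 0 fell and 18 did not pass, and 6 rose and 3 fell when adjusted over the list alone. Their median change was -0.0175, their mean 0.0528, and camera's p was 0.336 for a rise, and after centring on array medians the median was 0.0032. No shared rise was found among these 24, although Adk and Aprt rose by 0.62 and 0.32. Glutathione and redox genes may rise together: of 22 members not yet seen, 3 rose, 1 fell and 18 did not pass, with 6 higher and 1 lower when adjusted over the list alone. Their median was 0.0951, with a camera p of 0.00767, and p = 0.185 with an estimated correlation. After quantile normalization the median was 0.0434 with a p of 0.0843, so this stays open.

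Some genes of ribosome biogenesis were seen among the falls, and a hypothesis was that such genes fall together. The 11 members seen first had a median of -0.46. Of 64 others, 2 rose, 20 fell and 42 did not pass, and 4 rose and 35 fell when adjusted over the list alone. Their median was -0.148, with a camera p of 2.79e-11, and p = 0.0862 with an estimated correlation, which leaves a shared fall open. A shift of all genes of that brightness is argued against, since the list's median lay at percentile 0 of 10000 random lists matched on level, whose lowest median was -0.05. Scaling between arrays was tested by quantile normalization, after which the median was -0.196, and after centring it was -0.128. The median thus stayed below 0 under each scaling. Quantile normalization also lowered the glutathione median, from 0.0951 to 0.0434, and that of transfer RNA synthetases, from -0.119 to -0.174. The purine median went from -0.0175 to -0.0096. The larger fall after quantile normalization is therefore no evidence against scaling.

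Transfer RNA synthetases may fall together too. Of 18 members not yet seen, 5 fell, 0 rose and 13 did not pass, and 9 fell when adjusted over the list alone. Their median was -0.119, with a camera p of 0.000406, and p = 0.257 with an estimated correlation, so a shared fall stays open.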
